A study of Mus musculus with 11 samples.

How the data were processed

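The study mapped contacts between the genome and lamin B1, a filament protein of the nuclear lamina, with DamID-seq. In this assay the bacterial enzyme Dam (DNA adenine methyltransferase) is fused to LMNB1, so that DNA close to the lamina gains adenine methylation, and untethered Dam serves as the control for DNA that any free enzyme can reach. Per the labels' protocols, the cells were mouse oligodendrocyte precursor cells (OPC) from the cortex of C57BL/6 pups at postnatal day 7. They carried lentiviral Dam-LMNB1 or Dam for 1 day and were then kept for 72 h in proliferation medium (here OPC) or in differentiation medium (here OL, for oligodendrocyte). Methylated fragments were amplified by methylation-specific PCR and sequenced. The 11 libraries form 4 groups, which are OPC Dam-LMNB1 (3 libraries, numbered 8, 9 and 10), OPC Dam (2 libraries, 2 and 4), OL Dam-LMNB1 (3 libraries, 18, 19 and 20) and OL Dam (3 libraries, 12, 13 and 14).

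The authors deposited 1 table with a score for each of 21534 gene regions and each of the 6 Dam-LMNB1 libraries. Per the file headers, each score compares 1 Dam-LMNB1 library with the pooled Dam libraries of its own condition. Per the submitters' processing notes, cutadapt 1.9.1, BWA 0.7.17 and the mm10 build were used; how reads became scores is not given in the sources used here. The deposited scores take values on both sides of 0 with no stated log base, so differences are given in score units and never as folds. A score above 0 is read here as more Dam-LMNB1 than Dam methylation. Read depth is unknown, so no interval for counting error could be made. The authors also deposited a p-value per region, which equals a Welch test of the 3 OL scores against the 3 OPC scores within 0.5% in 100.0% of the regions, and an adjusted p-value with 1 blank value. The authors' adjusted p-value implies an adjustment over 33084 regions, more than the 21534 used here.

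The coordinates are those of the deposited table (mm10). In 70.5% of the regions the start lay within 100 bp of a point 10000 bp upstream of the annotated gene, and in 85.9% the end lay within 100 bp of a point 2000 bp downstream. A value therefore belongs to a gene with its flanks, and exons, introns and UTRs share it. The median width was 26.25 kb, and 63.9% of the regions overlapped a neighbour. Names and gene types came from a reference gene table of assembly GRCm38.p6, none of whose coordinates are printed. It matched 20996 regions, of which 19342 were protein-coding, and the list tests used 19117 protein-coding genes with 1 region each. Another 428 regions were tRNA genes and 110 had no match.

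Before the data were examined, the groups, the comparisons, the tests, the gene lists and the rule for named genes were fixed. That design assumed values for all 11 libraries, whereas the table holds scores of 6, so the branch written for normalized values was used on the scores as deposited, with no further logarithm, pseudocount or filter. limma 3.58.1 (R 4.3.3) was fitted to all 6 libraries with 1 mean per condition, a variance trend and 9.42 total degrees of freedom. Each condition's mean was tested against 0, and OL was tested against OPC, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the 21534 regions. All 3 scores of a condition share 1 pooled Dam denominator, so the replicate spread and every p-value leave out the variation between Dam libraries. The labels do not say whether libraries came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Comparisons of Dam-LMNB1 alone and of Dam alone between conditions were planned and are not analysed here.

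The share of regions past the threshold above 0 stood in for the share of the genome in lamina-associated domains (LADs), because the regions do not tile the genome. The share of regions above 0 per library was compared by an exact permutation test, which with 3 against 3 libraries cannot go below 0.1. Gene lists were tested with limma's camera, two-sided, with an estimated correlation between genes and adjustment over the 29 lists. A preset correlation of 0.01 was the alternative. The versions differ in more than the correlation, since the estimated version has only the few residual degrees of freedom of the libraries. For clustered protocadherins in OPC the estimated correlation was 1.39e-04, below 0.01. Their adjusted p was still 0.0223, against 7.66e-10 with the preset correlation (camera). The lists were OPC genes, myelin and oligodendrocyte genes, oligodendrocyte lineage transcription factors, cholesterol synthesis, cell cycle, neuronal genes, neurotransmitter receptors, voltage-gated ion channels, cell adhesion genes, astrocyte genes, microglia genes, endothelial and mural genes, muscle genes, liver genes, keratin and skin genes, nuclear lamina and envelope genes, heterochromatin enzymes, housekeeping genes, interferon and immune response genes and, by symbol pattern, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, replication-dependent histones, ribosomal proteins, zinc finger Zfp genes, bitter taste receptors, beta-defensins and keratin clusters.

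Named genes followed 1 rule per comparison. It took the 8 protein-coding genes with the largest positive and the 8 with the largest negative estimate among those past 0.05 whose libraries did not overlap the other side (0 or the other condition), without provisional symbols. It allowed at most 1 gene per 1 Mb and at most 2 genes with the same letters before the first digit. To these it added the 3 members of each list with the smallest p and always a set of lineage and lamina genes, among them Mbp, Mog, Myrf, Pdgfra, Cspg4, Olig2, Sox10 and Lmnb1. Not every gene that the rule took is named in the text. Runs are neighbouring regions on a chromosome that all passed 0.05 in 1 direction, and the 3 longest in each direction are given. Longest means the most regions, not the most Mb. The medians of 26 lists and of the tRNA genes were also set against 10000 random lists matched on mean score, for tRNA genes also on region width.

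Alternatives were quantile normalization across the 6 libraries, autosomes only, the libraries of 1 condition only, leaving out each library, equal mean and SD per library, equal median per library, no variance trend, protein-coding genes only and a Welch test per region. The fit was tested on simulated scores for 21534 regions, 200 of them changed. It called 0 of 50 regions changed by 0.25, 23 of 50 changed by 0.5, 48 of 50 changed by 1 and 49 of 50 changed by 1.5, and 5.51% of its calls were false. The simulated noise was independent between regions, and far fewer regions were changed than the 7308 called in the data. These rates therefore do not carry over to the data. The list test (limma's camera), on 19117 simulated genes, found a list of 40 genes moved by 0.3, and 0 of 100 unmoved lists had p under 0.05. Those genes were simulated without correlation, whereas the estimated correlation in the data was 0.12 for cell cycle and 0.43 for OPC genes. The simulation thus does not show what shift the list test can find in the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.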

Results

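Lamin B1 contacts were measured by DamID-seq in mouse OPC kept in proliferation medium and in cells moved to differentiation medium (OL). Scores of 6 Dam-LMNB1 libraries, 3 per condition, were analysed over 21534 gene regions (mm10), each score being taken by the authors against the pooled untethered Dam libraries of the same condition (2 in OPC, 3 in OL). Read depth is unknown. The scores had a low and a high group of regions, with 60.6% of the regions at a mean score from −4 to −1, 17.3% from −1 to 0.5 and 22.0% from 0.5 to 4. The mean score over regions was −0.92, −0.94 and −0.92 in OPC libraries 8, 9 and 10, and −0.79, −0.88 and −0.87 in OL libraries 18, 19 and 20. OL library 18 also had the narrowest range, with an SD over regions of 1.46 against 1.53 to 1.59 in the other 5 libraries. Across regions, which are not independent replicates, Pearson's r was 0.991 to 0.995 for the 6 pairs of libraries within a condition and 0.976 to 0.981 for the 9 pairs between conditions. The median absolute difference between libraries was 0.089 to 0.152 within and 0.200 to 0.269 between conditions. The first principal component held 63.4% of the variance and separated OPC from OL, and the second, with 13.5%, set OL library 18 apart from OL libraries 19 and 20.

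**Figure D1:**
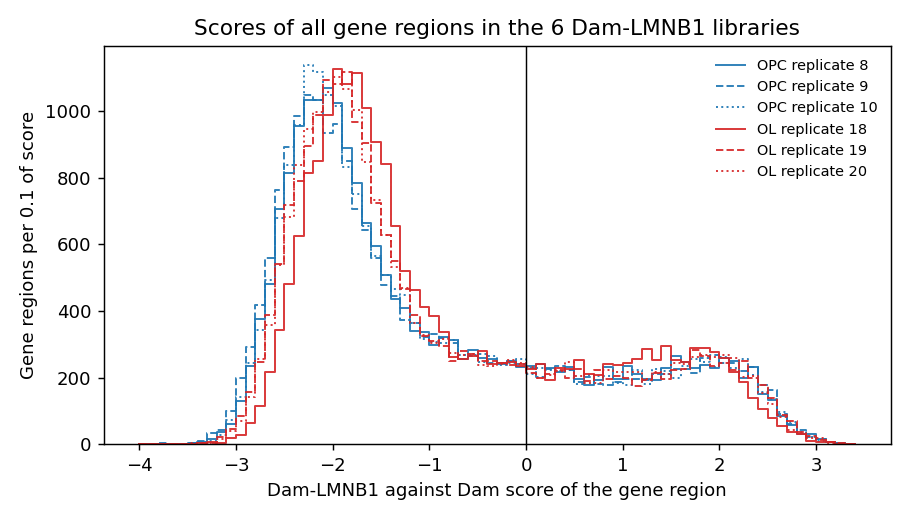
Number of gene regions per 0.1 score units (vertical axis) against the score (horizontal axis) in each of the 6 Dam-LMNB1 libraries. All 6 libraries have a low and a high group of regions, and 27.3%, 26.8% and 26.8% of the regions in OPC and 28.3%, 26.8% and 27.3% in OL lie above 0.

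The first comparison asked which genes lay at the lamina in OPC, by testing the mean score against 0. Under the naming rule, which allows 2 genes of a kind, the highest was the olfactory receptor Olfr802 (chr10:129679799-129692737) with a score of 3.30 ± 0.02 (SD, n = 3), followed by Olfr1289 at 3.21 ± 0.17 and the bitter taste receptor Tas2r102 at 3.19 ± 0.09. Next were the prolactin family gene Prl2c3 at 3.13 ± 0.03, the beta-defensin Defb18 3.0 ± 0.09, the cornified envelope gene Sprr2k 2.92 ± 0.06, the vomeronasal receptor Vmn1r28 2.92 ± 0.08 and Pydc3 2.89 ± 0.04. The lowest were the histone gene Hist1h4f (chr13:23549286-23561643) at −3.41 ± 0.26, Fyttd1 at −3.32 ± 0.02 and Paip2 at −3.27 ± 0.14. Next came the respiratory chain gene Sdhd at −3.24 ± 0.20, the splicing genes Sfpq at −3.23 ± 0.10 and Hnrnpa2b1 at −3.23 ± 0.12, Tmem265 at −3.21 ± 0.19 and Rsrc2 at −3.21 ± 0.23. All 3 OPC libraries lay on the same side of 0 for each of these genes, and the limma adjusted p (Benjamini-Hochberg) was 1.05e-10 for Olfr802 and 1.3e-10 for Hist1h4f.

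In OPC, 5493 regions lay above 0 and 15382 below 0 at an adjusted p under 0.05 (limma), 25.5% and the larger part of the 21534 regions. Of 1094 olfactory receptors 1047 were above 0 and 36 below, with a median score of 2.13, and of 316 vomeronasal receptors 313 were above and 2 below (median 1.97). Of 35 bitter taste receptors 35 were above 0 (median 2.47), of 41 beta-defensins 25 were above and 16 below, and of 22 clustered protocadherins 21 were above and 1 below (median 1.05). Neurotransmitter receptors had 25 of 35 members above 0 and 7 below (median 1.09), among them Grm7 at 2.07 and Gabra2 at 1.85. Cell adhesion genes had 29 of 43 above and 13 below, with Cntnap5a at 2.24 and Epha3 at 2.04. Voltage-gated ion channels had 17 of 33 above and 15 below, with Kcnc2 at 2.30 and Kcnd3 at −2.59. Keratin clusters had 61 of 105 above and 34 below, and keratin and skin genes 9 of 20 above and 9 below.

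Lineage genes lay mostly below 0 in OPC, as most regions did, and their lists did not pass the test against the other genes (camera, adjusted p from 0.551 to 0.793 with an estimated correlation). The estimated correlation was 0.43 for OPC genes, at which the test can miss a difference. With the preset correlation the adjusted p was 0.0686 for OPC genes, 0.34 for myelin genes and 0.0884 for lineage transcription factors (camera). OPC genes had 22 of 24 members below 0 and 2 above, with Ptprz1 at −2.90. Myelin and oligodendrocyte genes had 24 of 30 below and 5 above, with the axonal adhesion gene Nfasc at −2.32. Lineage transcription factors had 19 of 20 below and 1 above, which was St18 at 1.88 ± 0.02 (SD, n = 3). All 22 cholesterol synthesis genes, all 39 Hox genes and all 25 housekeeping genes were below 0. So were 31 of 32 cell cycle genes with 0 above, 65 of 66 histone genes with 0 above and 81 of 83 ribosomal protein genes with 2 above. Nuclear lamina and envelope genes had 18 of 20 below and 2 above, heterochromatin enzymes 21 of 22 below and 1 above, and zinc finger Zfp genes 264 of 362 below and 81 above. Of genes of other cell types, 10 of 30 neuronal genes were above and 17 below. Above 0 were 2 of 16 astrocyte genes with 13 below, 3 of 16 microglia genes with 12 below, and 7 of 16 endothelial and mural genes with 7 below. Also above 0 were 4 of 20 muscle genes with 14 below, 7 of 19 liver genes with 12 below and 2 of 18 interferon genes with 15 below. Adjusted over the list alone, the counts were the same in every list except keratin and skin genes, with 8 below 0.

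Against all other genes, 5 lists stood higher in OPC with an estimated correlation (camera). The adjusted p was 0.0223 for olfactory receptors, for clustered protocadherins and for neurotransmitter receptors, 0.0283 for beta-defensins and 0.0363 for vomeronasal receptors. The correlation comes from the spread between libraries, so it leaves out the score level that neighbours in a cluster share. It was 1.39e-04 for clustered protocadherins. For families in clusters these p-values count neighbours as separate genes and overstate the support. No list stood lower, although 7 did so with the preset correlation, and the bitter taste receptors had adjusted p = 0.0826 with an estimated correlation. Runs were ranked by number of regions, which favours gene-dense stretches. On that count the longest above 0 were chr2:85126360-90403674 (227 regions, median score 2.36), chr7:102524749-105371317 (146 regions, 2.02) and chr9:37657902-40152878 (101 regions, 2.14). All consist mainly of olfactory receptor genes. The longest below 0 were chr4:122826227-143423087 (358 regions, −2.13), chr17:23530915-33112704 (280 regions, −2.13) and chr2:24418551-36254271 (262 regions, −2.29). Leaving out 1 library left between 0 and 2 of the 5 list calls, 2 of them without OL library 18 and 0 without any other. A library less also leaves this test fewer degrees of freedom, so the loss does not show that the scores hinged on 1 library. Members of the receptor and defensin families have similar sequences, and how the authors placed reads between copies is not given in the sources used here, so single members are uncertain.

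The same question in OL gave similar leading genes. Among the genes taken by the naming rule, which allows 2 of a kind, the highest were Olfr297 (chr7:86516759-86529691) at 3.23 ± 0.06 (SD, n = 3), Olfr802 at 3.20 ± 0.04, Tas2r102 at 3.07 ± 0.06 and Sva at 2.99 ± 0.01. Next were the casein gene Csn1s1 at 2.92 ± 0.13, Defb18 at 2.90 ± 0.11, Vmn1r28 at 2.85 ± 0.07 and Prl2c3 at 2.84 ± 0.25. The lowest were Evi2b (chr11:79511385-79533762) at −3.26 ± 0.05, Hist1h4f at −3.23 ± 0.14, Ndfip1 at −3.16 ± 0.10, Fyttd1 at −3.13 ± 0.15 and Sdhd at −3.11 ± 0.09. Then came the ubiquitin-conjugating enzyme gene Ube2d2a at −3.11 ± 0.20, Nudt21 at −3.10 ± 0.04 and the kinase gene Csnk1d at −3.06 ± 0.14. All 3 OL libraries lay on the same side of 0 for each, and the limma adjusted p was 1.5e-10 for Olfr297 and 2.21e-10 for Evi2b.

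In OL, 5579 regions (25.9%) lay above 0 and 15266 below at an adjusted p under 0.05 (limma). Olfactory receptors had 1045 of 1094 above 0 and 40 below (median 2.02), vomeronasal receptors 313 of 316 above and 1 below (1.91) and bitter taste receptors 35 of 35 above. Beta-defensins had 25 of 41 above and 16 below, clustered protocadherins 21 of 22 above and 1 below and neurotransmitter receptors 25 of 35 above and 9 below (1.04), with Glra3 at 2.27. Cell adhesion genes had 31 of 43 above and 11 below, ion channels 16 of 33 above and 16 below, keratin clusters 54 of 105 above and 36 below and keratin and skin genes 8 of 20 above and 8 below. OPC genes had 2 of 24 above and 22 below, myelin genes 5 of 30 above and 25 below, with Sirt2 at −2.09, and lineage transcription factors 1 of 20 above and 19 below, again with St18 (1.9 ± 0.02, n = 3) as the exception. Cell cycle genes had 3 of 32 above and 29 below. All 22 cholesterol synthesis genes, 39 Hox genes, 25 housekeeping genes, 66 histone genes and 16 astrocyte genes were below 0, and 81 of 83 ribosomal protein genes were below with 2 above. Neuronal genes had 10 of 30 above and 16 below, microglia genes 4 of 16 above and 12 below, and endothelial and mural genes 7 and 7 of 16. Muscle genes had 4 of 20 above and 14 below, liver genes 7 of 19 above and 12 below, and interferon genes 1 of 18 above and 16 below. Nuclear lamina and envelope genes had 2 of 20 above and 18 below, heterochromatin enzymes 1 of 22 above and 21 below and zinc finger Zfp genes 84 of 362 above and 260 below. Adjusted over the list alone, every count was the same.

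The same 5 lists stood higher in OL with an estimated correlation (camera), with adjusted p = 0.0243 for olfactory receptors, clustered protocadherins and neurotransmitter receptors, 0.0358 for beta-defensins and 0.0380 for vomeronasal receptors. Here too the estimated correlation leaves out the score level that neighbours in a cluster share. No list stood lower, while 8 did so with the preset correlation. The runs above 0 had median scores of 2.31 at chr2:85126360-90403674 (227 regions), 1.88 at chr7:102524749-105371317 (146 regions) and 2.11 at chr9:37657902-40190094 (102 regions). Those below 0 had median scores of −1.95 at chr4:122826227-143423087 (358 regions), −1.85 at chr17:23530915-33112704 (280 regions) and −2.01 at chr2:24788769-36254271 (260 regions). As in OPC, leaving out any library but OL library 18 left 0 of the 5 list calls, and 2 were left without that library. The same loss of degrees of freedom applies.

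The third question was whether the share of genes at the lamina differed between the conditions. Over libraries, 27.0% ± 0.266 (SD, n = 3) of the regions had a score above 0 in OPC and 27.4% ± 0.755 (n = 3) in OL. The difference of 0.452 percentage points was within the spread between libraries (exact permutation test, two-sided p = 0.7, smallest possible 0.1). In all 6 libraries together, 5332 regions (24.8%) were above 0 and 15079 (70.0%) below 0, and 5.22% had both signs. By chromosome, the share above 0 was highest among autosomes and X on X, with 47.3% ± 0.314 in OPC and 50.9% ± 0.598 in OL, and lowest on chromosome 11, with 12.5% ± 0.225 and 11.8% ± 0.689 (SD, n = 3 each).

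The fourth question was which genes had a higher or lower score in OL than in OPC. Such a difference can come from Dam-LMNB1 or from Dam methylation, which were not compared on their own. Among the genes taken by the naming rule, the largest rise in score was that of Trim24, which encodes a chromatin reader (chr6:37860811-37970445, −1.53 ± 0.04 in OPC and −0.15 ± 0.09 in OL, SD, n = 3, difference 1.38). Next was the myosin light chain gene Myl1 (chr1:66922296-66955056, −0.58 ± 0.09 and 0.72 ± 0.23, difference 1.31). Pcbp3 rose by 1.31, the fibrillin gene Fbn2 by 1.25 and Lnp by 1.21. The kinetochore gene Cenpk rose by 1.21 (from −0.45 ± 0.07 to 0.75 ± 0.06), Plk4, the kinase that starts centriole duplication, by 1.14 (from −0.93 ± 0.05 to 0.22 ± 0.10) and Abhd13 by 1.12. The largest falls in score under that rule were those of Mettl7b (chr10:128956277-128970988, 0.30 ± 0.23 in OPC and −1.31 ± 0.15 in OL, difference −1.61), Pcolce2 (−1.28) and Trp63, the p53 family factor of stratified epithelium (chr16:25673765-25894088, 1.14 ± 0.07 and −0.14 ± 0.10, difference −1.28). Cdc42ep3 fell by 1.25, the sodium-calcium exchanger Slc24a3 from 1.29 ± 0.01 to 0.09 ± 0.08, the kinesin Kif6 by 1.16, the semaphorin and VEGF co-receptor Nrp1 by 1.13 and Tmeff1 by 1.12.

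The OPC and OL libraries did not overlap for any of these 16 genes. The limma adjusted p was 5.95e-05 for Trim24, 1.84e-04 for Myl1, 1.15e-04 for Mettl7b and 5.95e-05 for Trp63, with 2.05e-03 for Abhd13 the highest. In all, 4963 regions were higher and 2345 lower in OL (67.9% of the 7308 calls higher), with a median change of 0.39 among the higher and −0.40 among the lower and a median SE of 0.09. Of these, 1113 rose by over 0.5 and 657 fell by over 0.5, and 28 and 27 moved by over 1 in the same directions. OPC and OL libraries did not overlap in 10524 regions (48.9%). A share of 10% would hold by chance only if the scores of both conditions could be swapped freely. The scores of a condition share their Dam denominator, so 10% is no measure of chance here. The median change over all regions was 0.10, and with each library set to the same mean and SD it was 0.02, with 3330 regions higher and 3261 lower (50.5% higher). That scaling itself removes the mean shift between the conditions. The authors' deposited table has 676 regions under its adjusted p of 0.05, 412 higher and 264 lower in OL, and 665 of the 676 were called here in the same direction. All p-values leave out variation between Dam libraries, since the scores of a condition share 1 pooled Dam denominator, and 63.9% of regions overlap a neighbour, so calls are not independent.

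**Figure D2:**
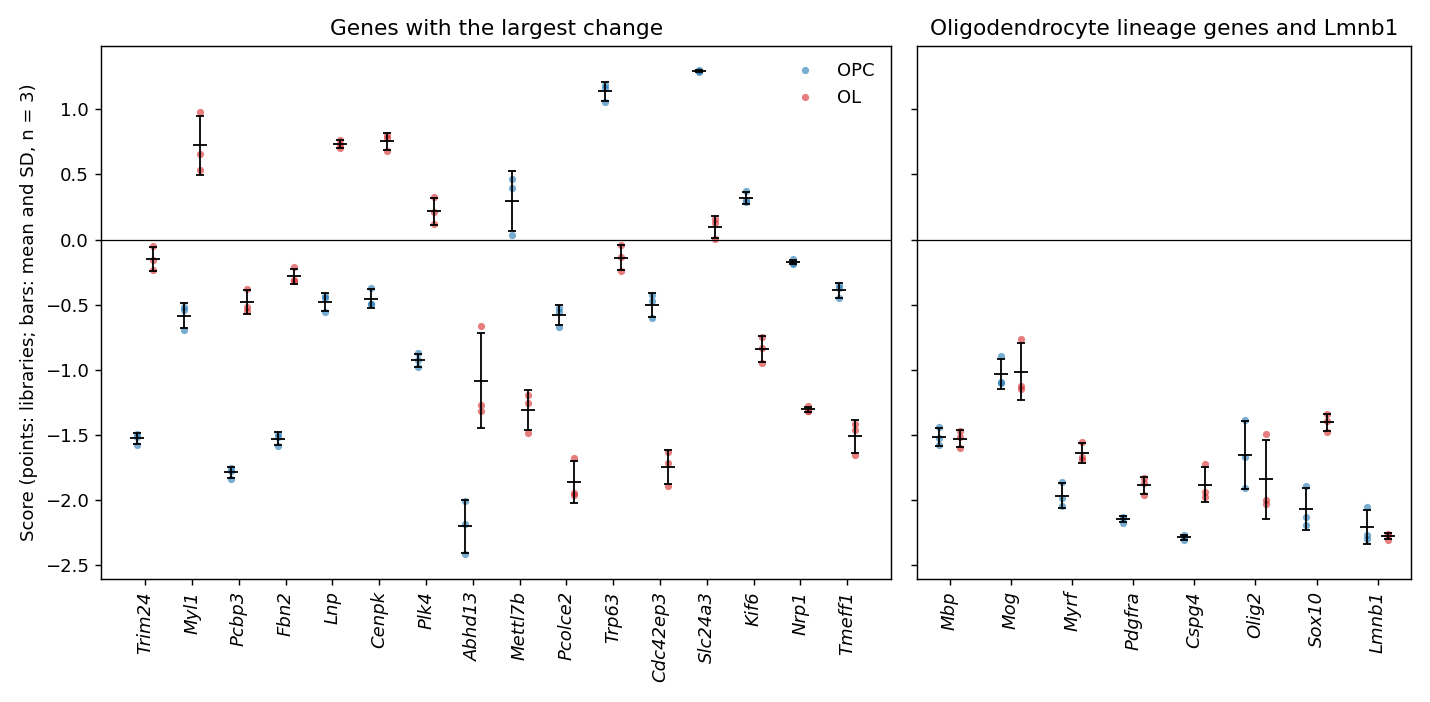
Score (vertical axis, score units) of the 16 genes with the largest change and of 8 lineage and lamina genes (horizontal axis), with 1 point per library in OPC and OL and the mean with SD of 3 libraries. Trim24 lies at −1.53 in OPC and −0.15 in OL, and Trp63 at 1.14 and −0.14, while Mbp lies at −1.51 and −1.53.

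Most changes took place without crossing 0. Of the 4963 higher regions, 3784 stayed below 0 in all 6 libraries, and of the 2345 lower regions 855 stayed above and 1233 below 0. A change from above 0 in all 3 OPC libraries to below 0 in all 3 OL libraries was called in 112 regions, including Mettl7b, Trp63 and Kif6, and the opposite in 150, including Myl1, Lnp, Cenpk and Plk4. With each library set to the same mean and SD these numbers were 137 and 125, so which of them was larger depended on the scaling. Chosen after their values were seen, other genes of this kind were the bone morphogenetic protein receptor Bmpr1b (0.16 to −0.88) and the potassium channel Kcnj2 (0.25 to −0.67), and in the other direction the cell cycle repressor E2f7 (−0.64 to 0.41) and the steroid reductase Akr1d1 (−0.25 to 0.82).

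Mbp, Mog, Myrf, Pdgfra, Cspg4, Olig2, Sox10 and Lmnb1, which the rule always takes, lay below 0 in both conditions. Sox10, the factor that drives myelin gene expression (chr15:79152913-79174506), rose from −2.07 ± 0.16 to −1.40 ± 0.07 (SD, n = 3, limma adjusted p = 1.69e-03), and the proteoglycan gene Cspg4 by 0.41, the myelin regulator Myrf by 0.33 and the growth factor receptor gene Pdgfra by 0.26 (adjusted p = 0.0333). The calls of Myrf and Pdgfra were lost under quantile normalization, with adjusted p = 0.0653 and 0.256, and that of Pdgfra also without any 1 of 5 of the 6 libraries. Differences of −0.01 for Mbp, 0.02 for Mog, −0.19 for Olig2 and −0.07 for Lmnb1 did not pass the test, with adjusted p from 0.409 to 0.925.

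Among OPC genes 8 of 24 rose, 4 fell and 12 did not pass (11 and 4 adjusted over the list alone, 6 and 4 with equal mean and SD, 6 to 8 and 2 to 4 without 1 library). Lhfpl3 rose by 0.98 (−1.35 ± 0.01 to −0.36 ± 0.04, SD, n = 3) and Pcdh15 by 0.61, and the lower members were Tnr (−0.50), Sox5, Sox6 and Egfr, the last 3 chosen after their values were seen. Of 30 myelin and oligodendrocyte genes 7 rose and 5 fell (8 and 5 adjusted over the list alone, 3 to 6 and 3 to 6 without 1 library), whereas 4 rose and 9 fell with each library set to the same mean and SD. Ppp1r14a rose by 0.60, and Mal, Aspa, Mobp and Enpp6, chosen after their values were seen, were among the lower members. Of 20 lineage transcription factors 4 rose and 0 fell (4 and 0 adjusted over the list alone, 3 to 4 and 0 to 1 without 1 library), which were Sox10, Myt1 (0.51), Zfp536 (0.33) and Sox2, the last chosen after its value was seen, but 3 rose and 2 fell with equal mean and SD. Of 22 cholesterol synthesis genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 5 to 6 and 1 without 1 library), among them lanosterol synthase Lss (0.65), Pmvk (0.62) and Cyp51 (0.47), but 5 rose and 4 fell with equal mean and SD. The lower one, Hmgcs1 (−0.55), was chosen after its value was seen. None of the 4 lists passed the test against the other genes (camera, adjusted p from 0.901 to 0.988 with an estimated correlation).

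Cell cycle genes had the highest median change of the 29 lists, 0.36. Of 32 members 20 rose, 0 fell and 12 did not pass (21 and 1 adjusted over the list alone, 16 to 19 and 0 to 1 without 1 library), and with each library set to the same mean and SD 13 rose and 1 fell. The mitotic kinesin Cenpe rose from 0.02 ± 0.07 to 0.78 ± 0.11 (SD, n = 3), the survivin gene Birc5 from −2.60 ± 0.02 to −1.81 ± 0.19 and the replicative helicase gene Mcm6 from −1.42 ± 0.02 to −0.95 ± 0.08. Of 39 Hox genes 22 rose and 1 fell (23 and 1 adjusted over the list alone, 16 and 1 with equal mean and SD, 15 to 21 and 0 to 1 without 1 library). Hoxd1 was up by 1.09, Hoxb2 by 0.48 and Hoxa10 by 0.48, and Hoxd13 (−0.41), chosen after its value was seen, was the lower one. By cluster 6 of 11 Hoxa, 9 of 10 Hoxb, 1 of 9 Hoxc and 6 of 9 Hoxd genes rose. Of 83 ribosomal protein genes 28 rose and 3 fell (29 and 3 adjusted over the list alone, 13 and 6 with equal mean and SD, 17 to 23 and 2 without 1 library). Rplp0 was up by 0.68 and Rpl3l by 0.49. With the preset correlation the adjusted p was 1.13e-04 for cell cycle genes, 4.29e-04 for Hox genes and 0.0481 for ribosomal proteins, but with an estimated correlation adjusted p = 0.559, 0.559 and 0.589 (camera).

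**Figure D3:**
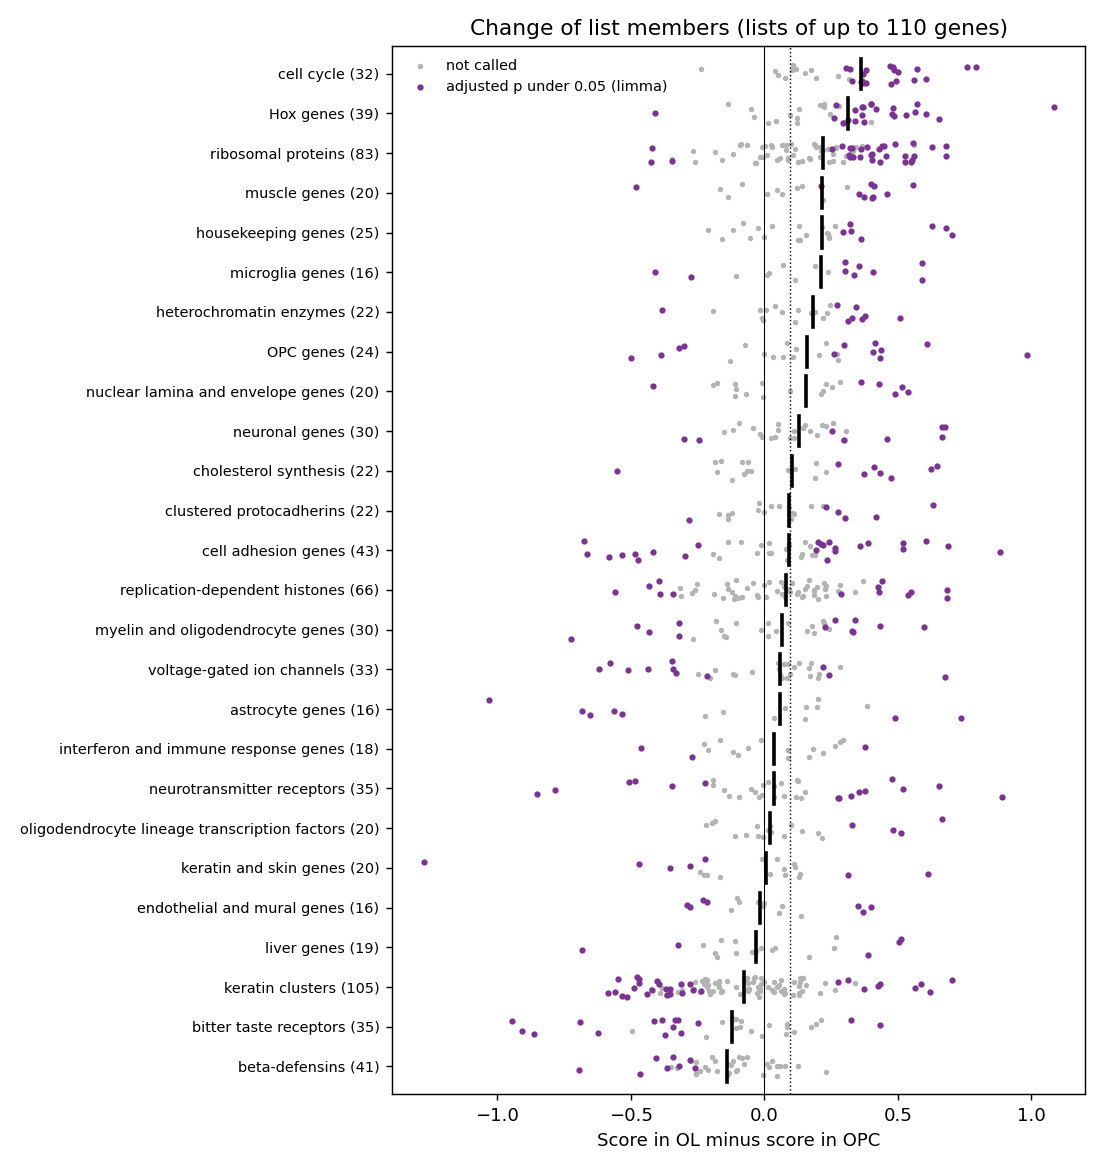
Change in score from OPC to OL (horizontal axis, score units) of each member of the 26 gene lists with at most 110 members (vertical axis), in purple where the limma adjusted p was under 0.05, with the list median as a bar and the median of all regions, 0.10, as a dotted line. Cell cycle (median 0.36) and Hox genes (0.31) lie farthest above that line, and beta-defensins (−0.14) farthest below.

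Synaptic and adhesion genes also moved in both directions. Of 35 neurotransmitter receptors 9 rose and 6 fell (9 and 6 adjusted over the list alone, 8 and 9 with equal mean and SD, 6 to 8 and 5 to 8 without 1 library). The muscarinic receptor Chrm3 rose from 0.63 ± 0.01 to 1.52 ± 0.04 (SD, n = 3) while the GABA-A subunit genes Gabrb1 (1.61 ± 0.01 to 0.83 ± 0.01) and Gabra4 (1.86 ± 0.05 to 1.01 ± 0.09) fell. Of 33 voltage-gated ion channels 3 rose and 8 fell (4 and 8 adjusted over the list alone, 5 and 11 with equal mean and SD, 1 to 3 and 6 to 10 without 1 library). Of the potassium channels Kcnd2 was up by 0.68, Kcnj16 down (−0.62) and Kcnh1 down (−0.58). Of 43 cell adhesion genes 15 rose and 9 fell (15 and 9 adjusted over the list alone, 17 and 10 with equal mean and SD, 8 and 10 with equal medians, 7 to 17 and 8 to 10 without 1 library). Lrrtm3 was up by 0.88, Pcdh9 by 0.69 and Cdh20 down (−0.68). Of 30 neuronal genes 6 rose and 2 fell (6 and 2 adjusted over the list alone, 5 and 4 with equal mean and SD, 3 to 6 and 1 to 2 without 1 library). Syt4 was up by 0.68, Tubb3 by 0.67 and Neurod1 by 0.66. Among the lower ones was Nrxn3 (−0.30), chosen after its value was seen. Of 22 clustered protocadherins 5 rose and 1 fell (5 and 1 adjusted over the list alone, 6 and 1 with equal mean and SD, 2 to 6 and 0 to 1 without 1 library), with Pcdhb1 up by 0.63. None of these lists passed the test against the other genes with an estimated correlation (camera, adjusted p from 0.559 to 0.988).

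Of 16 astrocyte genes 5 fell and 2 rose, while the median change was 0.06 and 9 of the 16 lay above 0 (5 and 2 adjusted over the list alone, 7 and 1 with equal mean and SD, 5 and 1 to 2 without 1 library). The connexin gene Gjb6 fell from −0.50 ± 0.18 to −1.53 ± 0.11 (SD, n = 3), the water channel Aqp4 from 0.13 ± 0.11 to −0.55 ± 0.01 and the bicarbonate transporter Slc4a4 from −0.09 ± 0.04 to −0.74 ± 0.06. The others, Gja1, Slc1a2 and, higher, S100b and Fgfr3, were chosen after their values were seen. Of 16 microglia genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, 4 and 2 with equal mean and SD, 4 to 6 and 1 to 2 without 1 library), with the purinergic receptor P2ry12 up by 0.59, Spi1 by 0.59 and Ptprc by 0.35. Of 16 endothelial and mural genes 3 rose (Kdr by 0.35, Vtn by 0.40 and Esam by 0.37) and 4 fell (3 and 4 adjusted over the list alone, 2 and 3 with equal mean and SD, 2 to 3 and 0 to 2 without 1 library). Of 20 muscle genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, 6 and 1 with equal mean and SD, 4 and 2 with equal medians, 4 to 7 and 0 to 1 without 1 library). Ryr1 was up by 0.41, Ckm by 0.41 and Tnnt2 by 0.40. Of 19 liver genes 3 rose and 2 fell (2 and 2 adjusted over the list alone, 2 and 3 with equal mean and SD, 2 to 3 and 2 to 4 without 1 library). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was up by 0.50, Apoa1 up by 0.51 and Cyp3a11 down (−0.68). Of 20 keratin and skin genes 2 rose and 5 fell (2 and 5 adjusted over the list alone, 1 and 6 with equal mean and SD, 1 to 2 and 2 to 4 without 1 library), with loricrin Lor up by 0.61 and Trp63 and Krt14 (−0.47) down. None of these lists passed the list test with an estimated correlation (camera, adjusted p from 0.559 to 0.749).

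Of 20 nuclear lamina and envelope genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, 4 and 4 with equal mean and SD, 4 to 5 and 0 to 1 without 1 library). Tmpo was up by 0.52, Sun2 by 0.49 and Nup210 by 0.43. Of 22 heterochromatin enzymes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 3 and 2 with equal mean and SD, 3 to 6 and 1 without 1 library), with the maintenance DNA methyltransferase Dnmt1 up by 0.51, the Polycomb methyltransferase Ezh2 by 0.38 and Prdm16 down (−0.38). Of 25 housekeeping genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, 3 and 1 with equal mean and SD, 4 to 6 and 0 without 1 library). Tbp was up by 0.70 and Rplp0, also a ribosomal protein gene, by 0.68. Of 18 interferon and immune response genes 1 rose (Cxcl10, 0.38) and 2 fell, Rsad2 (−0.46) and Ifit3 (−0.27), against 1 and 1 adjusted over the list alone, 0 and 3 with equal mean and SD and 0 to 2 and 1 to 4 without 1 library. Of 66 histone genes 8 rose and 5 fell (7 and 3 adjusted over the list alone, 5 to 9 and 1 to 5 without 1 library), but 6 rose and 10 fell with equal mean and SD. Hist1h3e was up by 0.68. Of 362 zinc finger Zfp genes 78 rose and 27 fell (71 and 25 adjusted over the list alone, 45 and 37 with equal mean and SD, 47 to 64 and 18 to 26 without 1 library). Zfp948 was up by 0.58 and Zfp345 down (−0.64). These lists had adjusted p from 0.765 to 0.901 with an estimated correlation (camera).

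Calls in 5 families of tandem genes were more often lower than higher, with numbers that depended on the scaling and the test. The same holds for all regions with a mean score from 2 to 4, of which 9.08% were higher and 18.5% lower. That bin is no background for every family. Keratin clusters had a median score of 0.32 in OPC and 0.25 in OL, and 16 of 41 beta-defensins lay below 0. Of all regions with a mean score from 0 to 1, 25.2% were higher and 15.5% lower, and from 1 to 2 14.3% and 16.5%. Of 1094 olfactory receptors 101 rose and 214 fell (100 and 206 adjusted over the list alone, 125 and 167 with equal mean and SD, 42 and 226 with equal medians, 64 to 139 and 143 to 207 without 1 library). Olfr287 fell from 0.15 ± 0.14 to −0.77 ± 0.02 and Olfr480 from 2.76 ± 0.08 to 1.89 ± 0.15 (SD, n = 3), and Olfr11 rose by 0.69. Of 316 vomeronasal receptors 25 rose and 48 fell (21 and 42 adjusted over the list alone, 37 and 40 with equal mean and SD, 7 and 53 with equal medians, 13 to 34 and 35 to 56 without 1 library). Vmn2r12 was down (−0.62) and Vmn1r191 up by 0.58. Of 35 bitter taste receptors 2 rose and 13 fell (2 and 14 adjusted over the list alone, 4 and 9 with equal mean and SD, 2 to 3 and 9 to 12 without 1 library), with Tas2r121 (−0.95) and Tas2r115 (−0.91). Of 41 beta-defensins 0 rose and 8 fell (0 and 7 adjusted over the list alone, 0 and 11 with equal mean and SD, 0 to 1 and 5 to 8 without 1 library), with Defb45 (−0.69) and Defb20 (−0.47). Of 105 genes matched to the keratin clusters 9 rose and 22 fell (9 and 21 adjusted over the list alone, 9 and 28 with equal mean and SD, 4 to 8 and 14 to 24 without 1 library), with Krtap10-10 up by 0.62. The symbol pattern also took Krtcap2 (0.59), which is not a keratin gene. With the preset correlation these 5 lists had adjusted p = 3.26e-06, 8.73e-05, 1.53e-04, 1.71e-05 and 8.17e-05, but with an estimated correlation adjusted p = 0.559, 0.589, 0.559, 0.132 and 0.559 (camera).

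With an estimated correlation 0 of the 29 lists passed for the change (camera), and 1, the beta-defensins, had an unadjusted p under 0.05 (0.00454). That version of the test has few degrees of freedom with these libraries, so the 0 does not show that no list moved. With the preset correlation 3 stood higher and 5 lower. In 8 lists the median change was above 0 while the test's direction, relative to other genes, was lower, namely myelin genes, neurotransmitter receptors, ion channels, cell adhesion genes, astrocyte genes, keratin and skin genes, interferon genes and histones.

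Neighbouring genes often moved together. Runs are again ranked by number of regions. The longest run of higher regions lay at chr10:76022612-77979872, with 31 regions over 1.96 Mb from Zfp280b to Trpm2, among them Lss, Pcbp3 and the collagen genes Col6a1, Col6a2 and Col18a1. Its median score was −1.58 in OPC and −0.87 in OL, with a median change of 0.51. The next were chr10:80407165-80823498 (20 regions from Tcf3 to Jsrp1, median change 0.39) and chr1:58383136-59247231 (17 regions starting at Bzw1, with the apoptosis genes Casp8 and Cflar, 0.47). The longest runs of lower regions were chr9:92240194-96325646 (17 regions from Plscr1 to Tfdp2 over 4.09 Mb, −0.43), chr11:109223355-111078825 (16 regions from Rgs9 to Kcnj2, with 5 ABC transporter genes of the Abca group, −0.56) and chr6:135055662-136791742 (12 regions from Gprc5a to Gucy2c, −0.47). By chromosome, chromosome 19 had 33.0% of its regions higher and 5.07% lower, and chromosome 10 had 32.3% higher and 7.32% lower.

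**Figure D4:**
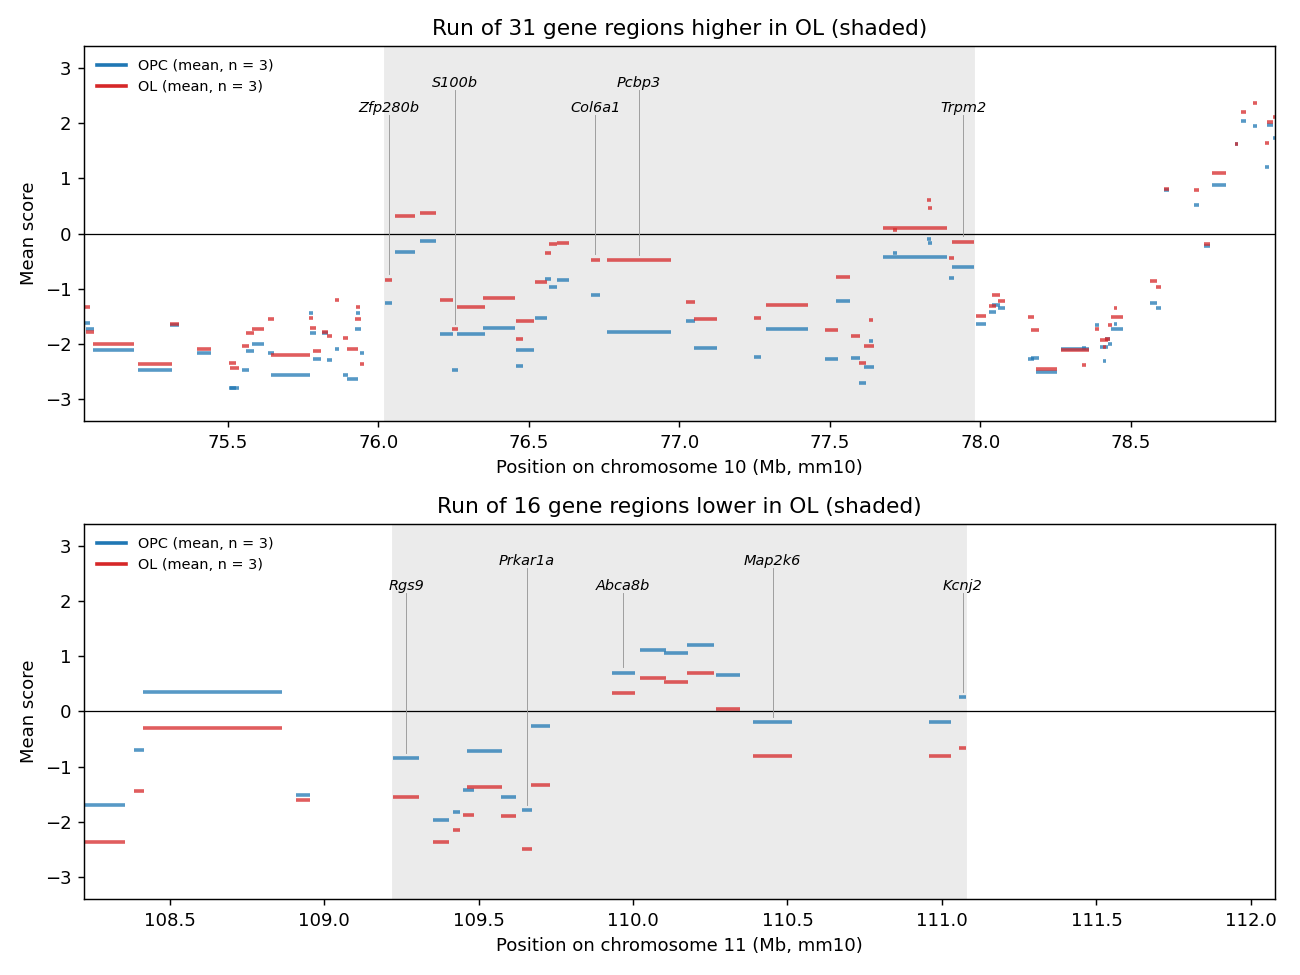
Mean score of 3 libraries (vertical axis, score units) of each region in OPC and OL against its position (horizontal axis, Mb) around the longest run of higher regions on chromosome 10 (31 regions) and the run of 16 lower regions on chromosome 11, both shaded. In the shaded spans the median score goes from −1.58 in OPC to −0.87 in OL on chromosome 10 and from −0.23 to −1.07 on chromosome 11.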

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

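The scalings to an equal mean and SD or an equal median, the fit without a variance trend, the protein-coding set, the Welch test per region and quantile normalization for the list tests were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Counts of regions above or below 0 in OPC and in OL stayed within 1.5 times under every alternative run. Of the 7308 changed regions, 73.7% were called in the same direction under quantile normalization, 73.9% with equal mean and SD, 79.8% with equal medians, 97.1% without a variance trend, 63.8% to 79.7% without 1 library and 12.4% by the Welch test per region, and none in the opposite direction. The Welch test called 566 regions higher and 359 lower (925 in all; 7047 at an unadjusted p under 0.05), since it estimates each region's spread from its own scores alone. The loss reached every list. It called 9 olfactory receptors higher and 9 lower, 1 and 6 vomeronasal receptors, 1 and 1 bitter taste receptors, 6 and 3 cell adhesion genes, 4 and 3 neurotransmitter receptors, 2 and 2 ion channels and 3 and 3 Zfp genes. It called 5 and 0 Hox genes, 3 and 0 ribosomal proteins, 2 and 0 each of cell cycle, OPC and neuronal genes, 2 and 1 myelin genes, 0 and 2 astrocyte genes, 1 and 1 liver genes and 0 and 1 keratin and skin genes. Lineage transcription factors, cholesterol synthesis, microglia and housekeeping genes had 1 and 0 each. Endothelial, muscle, lamina and envelope, heterochromatin, interferon, protocadherin, histone, beta-defensin and keratin cluster lists had 0 and 0. Without 1 library, 3136 (without OPC library 9) to 4132 (without OL library 19) regions were higher and 1673 to 2552 lower; the lowest falls short of the 4963 by over 1.5 times. The split was 3348 higher and 3278 lower under quantile normalization and 4029 and 2552 without OL library 18. Of the 108 named genes 103 were called for the change, and none of them reversed; 59 lost the call under the Welch test and at most 5 under any other alternative. In OPC and OL every named gene kept its call in all settings run.

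The share of regions past the threshold above 0 in OPC, 25.5%, was 25.8% under quantile normalization, 24.7% on autosomes, 26.0% with equal medians, 27.0% when each library's regions above 0 were counted and 24.99% to 25.6% without 1 library. In OL, 25.9% became 25.005% on autosomes and 27.4% by regions above 0. Lists higher in OPC went from 5 to 10 with the preset correlation and to 0 to 2 without 1 library, and lists lower from 0 to 7 with the preset correlation and 3 under quantile normalization. In OL the same numbers were 10, 0 to 2, 8 and 2. Under quantile normalization the 5 higher lists stayed in OPC and in OL. Bitter taste receptors joined them (adjusted p = 0.01975 in OPC and 0.0204 in OL, camera), as did keratin clusters in OPC (0.0355). For the change, 0 lists became 3 higher and 5 lower with the preset correlation. None passed under quantile normalization, with adjusted p = 0.189 for cell cycle and for Hox genes (camera). The preset correlation and a library left out also change the degrees of freedom of the list test. Other causes were not tested. Count scalings and count tests, filters, pseudocounts, 50, 100 and 200 kb windows, hidden Markov models, another gene value, single Dam libraries left out and both comparisons without the Dam ratio were planned and not run, since they need values other than these scores. Depth is unknown, so what it limits cannot be stated. In simulated scores, with 200 of 21534 regions changed and independent noise, a change of 0.25 was not found in any of 50 regions. Far more regions were called in the data, so this sets no lower limit on the changes found there.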

Other observations

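Chosen after the result was seen were the tests on equal mean and SD for the imbalance and for the changed regions, the splits of the libraries and the correlation between neighbours. The others were written before their tests were run, but for cell cycle genes after the higher members had been counted. Of 428 tRNA regions 117 were higher and 19 lower in OL (limma), with a median change of 0.15, which was the 99.6th percentile of 10000 sets matched on mean score and region width. That lies between the bounds set for the test, so a trend with level and width stays undecided. Over 135 loci of 1 Mb the median of the tRNA change was 0.12 (76.4% of that over all tRNA regions) and 101 of the loci lay above 0. The largest locus, chr13:21151405-22006652, held 52 tRNA regions, 34 of them higher, with a median change of 0.56, and without it the median was 0.13. Of 104 snoRNA regions 31 were higher and 7 lower (median change 0.23), and of 1032 miRNA regions 255 were higher and 92 lower. Counts in these gene types are to be read against all 21534 regions, of which 4963 (23.0%) were higher and 2345 lower. On the Y chromosome 0 of 27 regions were higher and 11 lower.

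More regions were higher than lower in OL (67.9% of calls). For regression to the mean from noise between libraries, replicate libraries of a condition had a mean slope of 0.993 (0.944 to 1.04 over 12 ordered pairs) and OL on OPC had 0.942. The mean over both orders of a pair evens out differences in SD, whereas the slope of OL on OPC keeps the smaller SD of OL. The 0.993 shows only that replicates resembled each other closely, and the lowest replicate slope was near 0.942. The slopes therefore do not decide on this explanation. The range and centre of the scores cannot be told apart from a change in most regions as the source of the imbalance. The share of higher calls was 50.5% with each library set to the same mean and SD and 51.2% with equal medians, but centring by itself brings the split close to even, so neither value decides. The median change went from 0.16 for regions with a mean score from −4 to −2 down to −0.05 for those from 2 to 4. Whether that narrower range comes from the Dam libraries, from the authors' scaling or from the cells in differentiation medium stays open and was not tested.

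Single regions differed between OL and OPC (7308 calls). The range and centre of the scores are argued against as the whole cause, since 73.9% of the calls were found in the same direction with equal mean and SD. The pooled Dam libraries, which every score of a condition shares, add counting noise. Such noise is argued against as the whole cause only where it is independent between regions. The change of neighbouring protein-coding genes that do not overlap and lie under 50 kb apart correlated with Pearson's r = 0.514 over 7159 pairs. Differences between replicate libraries gave at most 0.231, but the shared Dam term cancels in them, so they do not measure Dam noise. How reads became scores is not known, so noise that neighbours share through the scoring stays open. Of the 10 splits of the 6 libraries only 1, the real one, gave as many calls. The highest of the others gave 0 (limma, up to 512 regions at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split also mixes scores with different Dam denominators, so the splits cannot show that the calls exceed chance. A systematic difference between the Dam libraries of the conditions, which could follow domains as well, and a biological difference with the medium both stay open, untested.

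Of 32 cell cycle genes 20 were called higher in OL (limma; 2 by the Welch test), with a list median of 0.36 against 0.10 over all regions. As a list they did not pass, with adjusted p = 0.559 with an estimated correlation (camera). A trend of the change with the level of the score is argued against, since the list median lay at the 100th percentile of 10000 lists matched on mean score, whose median was 0.14. The same comparison, run for 26 lists, gave percentile 100 for Hox genes, 99.39 for ribosomal proteins, 1.2 for histones, 0.29 for beta-defensins and 0.15 for keratin clusters. Hox, histone, defensin and keratin genes lie in clusters, where neighbours move together, so random scattered genes understate their spread, and with an estimated correlation these 5 lists had adjusted p from 0.132 to 0.901 (camera). The range and centre of the scores are argued against as the whole cause, since 13 of the members were called higher with equal mean and SD. Whether the Dam libraries or the cells in differentiation medium account for these calls stays open and was not tested.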
